A study of Homo sapiens with 7 samples.

How the data were processed

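Transcripts were measured in single cells of frozen PBMC from 7 patients, 3 with sepsis and ARDS and 4 with sepsis only. Per the labels' protocols, libraries were made with 10x Genomics Single Cell 3' chemistry version 2, with 7000 cells loaded per sample, and processed with Cell Ranger 3.0.2. Per the submitters' processing notes, reads were mapped to hg19 and cells were filtered with Seurat 3.0 on genes per cell, mitochondrial share and hemoglobin share. The deposited values were whole-number UMI counts for 21212 genes, with 1 table per library. The labels give 24806 cells after quality control with 50419 mean reads per cell, and the tables held 24806 barcodes. The labels' wording of the filter at 3000 genes per cell can be read as removing cells below it, whereas every cell in the tables had fewer than 3000 genes, under 20% mitochondrial and under 10% hemoglobin UMIs. A further sequencing of 3212 cells at 182364 reads per cell that the labels mention was not among the tables. The reference at hand was of another genome build, so no coordinates are given and genes carry the names in the tables.

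Of the 21212 genes, 21012 were used: 174 that tell of a person (Y-linked genes, XIST, TSIX and the variable, diversity and joining segments of antigen receptors) and 26 with date-like or repeated names were left out. Cells with at least 200 genes, at most 20% mitochondrial and at most 10% hemoglobin UMIs were kept (24796). Scrublet's automatic threshold called 104 doublets (0.419%), so the 3% of cells with the highest doublet score in each library were taken as doublets instead. Clustering and the naming of clusters ran on all 24796 cells. The doublets were then removed before cells were counted and summed by class, which left 24052. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 31 clusters, or 63 with the sub-clusters of those that were mixed (scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, figures with matplotlib 3.10.9). A marker list's score was its mean log2 ratio to the median cluster with a pseudocount of 20 CPM, and a list counted with at least 3 markers in more than 0.1 of the cells and a score of at least 1. A cluster took the name of the highest list where every other list scored below 0.6 of it, and stayed unnamed where an unrelated list did not. Related lists (T with NK, and both monocyte lists with the dendritic list) were allowed to be closer: the one with most genes among the 10 leading genes gave the name, and the higher score decided ties. A T and NK mix that this rule would have named NK stayed unnamed. The exception named 5 clusters (6 and 7 T cell-like, 17 and 25 nonclassical, 27 dendritic cell-like). In clusters 25 and 27 the classical monocyte list scored higher than the list that gave the name (3.16 against 2.92, and 2.70 against 2.39), and all dendritic cell-like cells come from cluster 27. A cluster with more leading genes of another list (hemoglobin genes left out), or with few UMIs per cell and no marker among its leading genes, stayed unnamed too. The names are of resemblance ("-like"), since no protein was measured. 14 clusters and sub-clusters that held monocyte and platelet genes together stayed unnamed. Naming each cell by its own markers gave the same class for 75.9% of cells.

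UMIs were summed per library and class, since patients and not cells are the replicates, and libraries with fewer than 20 cells of a class were left out. The sums held 1471151 to 8317036 UMIs per library in classical monocyte-like cells, 2061458 to 7759241 in T cell-like, 73133 to 921834 in NK cell-like, 327770 to 1576040 in B cell-like and 5990756 to 14312075 in all PBMC summed. Groups were compared with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood test) and with DESeq2 1.42.0, in R 4.3.3. The SE of a log2 fold change is its size divided by the square root of the F value. Mean ± SD values are CPM over the libraries of a group. The common biological coefficient of variation was 0.465 to 0.517. The difference of the effect between monocytes and T cells was tested with limma 3.58.1 on the within-library difference of log2 CPM (prior count 2). Gene lists were tested with camera (limma) at its preset correlation of 0.01, with an estimated correlation and with fry as alternatives, for lists with at least 3 measured members. Shares of cells were compared by an exact permutation test over all 35 splits. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and over lists the adjustment ran within each class. Camera and fry rest on the fit across all genes.

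The groups, tests, alternatives, marker lists and 25 gene lists were fixed before the data were examined. The gene lists were type I interferon-stimulated genes, NF-kB and TNF inflammatory response, JAK-STAT and cytokine feedback, MHC class II presentation, MHC class I presentation, S100 alarmins and sepsis monocyte state, glucocorticoid-responsive genes, glycolysis and hypoxia response, nuclear-encoded oxidative phosphorylation, pattern recognition and inflammasome, scavenger and phagocytosis receptors, coagulation and fibrinolysis, cell stress and immediate early genes, apoptosis regulators, neutrophil granule genes, platelet genes, erythroid genes, T and NK lymphocyte genes, B and plasma cell genes, cytotoxic effector genes, T cell exhaustion and inhibitory receptors, naive and memory T cell genes, cell cycle, mitochondrially encoded mRNAs and cytosolic ribosomal proteins. The last list took every gene whose name starts with RPS or RPL, ribosomal S6 kinases included. Of the 15 T and NK lymphocyte genes, 6 also stand among the cytotoxic effector genes or the naive and memory genes, and none of the 15 platelet or 16 B and plasma cell genes stands in another list.

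Genes were named by a fixed rule: in each class up to 10 genes a direction (5 outside monocytes) with the smallest p among those past the threshold, filled to 10 in classical monocyte-like cells with the smallest unadjusted p, and the 3 members of each list with the smallest p in that class. Of these, the text prints the members of called lists and of a few others, and 1 gene is not reported here. The 2 libraries that stand apart were found after the data were examined, and the settings built on them, as well as the setting with the mixed monocyte and platelet clusters, were added then. Alternatives covered the scaling, the low count filter, the test, doublet removal, thinning to equal cells and 1000 UMIs per cell, naming by cell, both monocyte subsets together, a mitochondrial limit of 10% and each library left out in turn.

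The tests were tried on simulated counts drawn at the real libraries' means, sizes and fitted spread, with 200 genes changed. Of simulated 8-fold changes the test recovered 83.3% in T cell-like, 71.2% in B cell-like and 83.3% in all PBMC summed, of 4-fold changes 44.8%, 31.3% and 29.9%, and of 2-fold changes 7.46%, 1.49% and 1.49%. For the difference between monocytes and T cells it recovered 45.5% of 8-fold, 4.48% of 4-fold and 0 of 2-fold changes. In each class a planted list was called and 0 of 19 unchanged lists were. The simulated genes were drawn independently and no libraries were set apart. In the real counts the estimated correlation of the interferon list in classical monocyte-like cells was 0.872. The simulation therefore does not show how often camera calls unchanged lists in the real counts, and recovery of genes there may differ. No pair of libraries in a group was a copy: chi-square per degree of freedom was 33.9 to 146.4. Intervals and limits for shares cover counting error only.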

Results

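Frozen peripheral blood mononuclear cells (PBMC) of 7 patients were profiled by droplet single-cell RNA sequencing, in which unique molecular identifiers (UMIs) count the transcripts caught in each cell. Of the patients, 3 had sepsis with acute respiratory distress syndrome, a form of lung failure (ARDS; group sepsis_ARDS, libraries 1 to 3), and 4 had sepsis without it (group sepsis_only, libraries 1 to 4). The numbers name different patients in each group, and each patient gave 1 library. The deposited tables of sepsis_ARDS 1, 2 and 3 held 4118, 3551 and 2031 cells with 10873836, 8028646 and 6283990 UMIs. Those of sepsis_only 1, 2, 3 and 4 held 3943, 3351, 3852 and 3960 cells with 13264942, 11768542, 14988483 and 12908262 UMIs. The median cell held 2379, 2217 and 2842 UMIs in the sepsis_ARDS libraries and 2899, 3085, 3575 and 2867 UMIs in the sepsis_only libraries. After clustering, 24052 cells were used, and clusters were named by marker genes (classical monocyte-like, T cell-like and so on).

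The first comparison asked whether the make-up of the blood cells differed between the groups. Classical monocyte-like cells made up 32.9 ± 4.50% of the cells in sepsis_ARDS and 35.05 ± 25.4% in sepsis_only (mean ± SD, n = 3 and 4, exact permutation p = 0.914, two-sided). The sepsis_only libraries ranged from 10.4% to 63.1%, and the 3 sepsis_ARDS libraries lay between 29.5% and 38.0%. These shares depend on the naming, since unnamed clusters with monocyte and platelet genes together are left out of them. Those clusters held 0.05%, 11.6% and 1.32% of the cells of sepsis_ARDS 1, 2 and 3. They held 3.27%, 4.86%, 7.82% and 0.391% of the cells of sepsis_only 1, 2, 3 and 4. T cell-like cells made up 41.5 ± 2.31% and 37.8 ± 14.9%, and B cell-like cells 9.92 ± 3.95% and 5.72 ± 4.26%. NK cell-like cells, innate cytotoxic lymphocytes, made up 3.49 ± 1.81% and 7.19 ± 4.65%. The NK share depends on the naming too. Cluster 6, led by CMC1, DUSP2, CD8A, CCL5 and NKG7, and cluster 7 scored for both T and NK lists and count as T cell-like, and 7 sub-clusters with markers of both, 89.0% to 100% from sepsis_only 3, stayed unnamed (438 of that library's 3732 cells, 11.7%, were unnamed in all). With each cell named by its own markers, NK cell-like cells numbered 422, 60 and 199 in sepsis_ARDS and 682, 456, 484 and 209 in sepsis_only, against 152, 53 and 101 and 520, 244, 118 and 172 by cluster. By either naming the mean share was lower in sepsis_ARDS (exact permutation p = 0.286 for each). Nonclassical monocyte-like cells, the CD16-positive patrolling subset, made up 4.30 ± 2.01% and 3.16 ± 0.62%, and their share of all monocyte-like cells was 11.4 ± 4.86% and 13.2 ± 10.3% (exact permutation p = 0.743).

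Dendritic cell-like cells, which present antigen to T cells, numbered 0, 2 and 0 in the 3 sepsis_ARDS libraries and 14, 50, 4 and 45 in the 4 sepsis_only libraries. Their share was 0.019 ± 0.034% against 0.796 ± 0.671% (exact permutation p = 0.114, Benjamini-Hochberg adjusted 0.754 over 12 classes). The counts of 0 among 3994 and 1970 cells allow shares of up to 0.0751% and 0.152% (3 counts, counting error only), and the 2 cells among 3442 gave 0.058% (95% exact Clopper-Pearson interval 0.007% to 0.21%). These counts follow the removal of the 3% of cells with the highest doublet score. Before it the cluster held 2, 2 and 2 cells of the sepsis_ARDS libraries and 17, 50, 8 and 46 of the sepsis_only libraries (exact permutation p = 0.0857), so the zeros arise from that step. The classical monocyte list scored higher in this cluster than the dendritic list (2.70 against 2.39), which gave the name through CLEC10A and FCER1A among the 10 leading genes. Every sepsis_only library lay above every sepsis_ARDS library by this naming. With each cell named by its own markers, dendritic cell-like cells numbered 45, 35 and 6 in sepsis_ARDS and 48, 126, 26 and 122 in sepsis_only, and the groups overlapped (exact permutation p = 0.229); 97 of these cells lay in the cluster. Plasmacytoid dendritic cell-like cells, known as interferon producers, made up 0.193 ± 0.171% against 0.057 ± 0.068% (exact permutation p = 0.257). No share passed after adjustment. The smallest p that 35 splits of 7 libraries allow is 0.0286, so no single share could pass alone after adjustment over 12 classes. A share is of the cells in the tables, so 1 class that is higher makes the others lower.

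**Figure D1:**
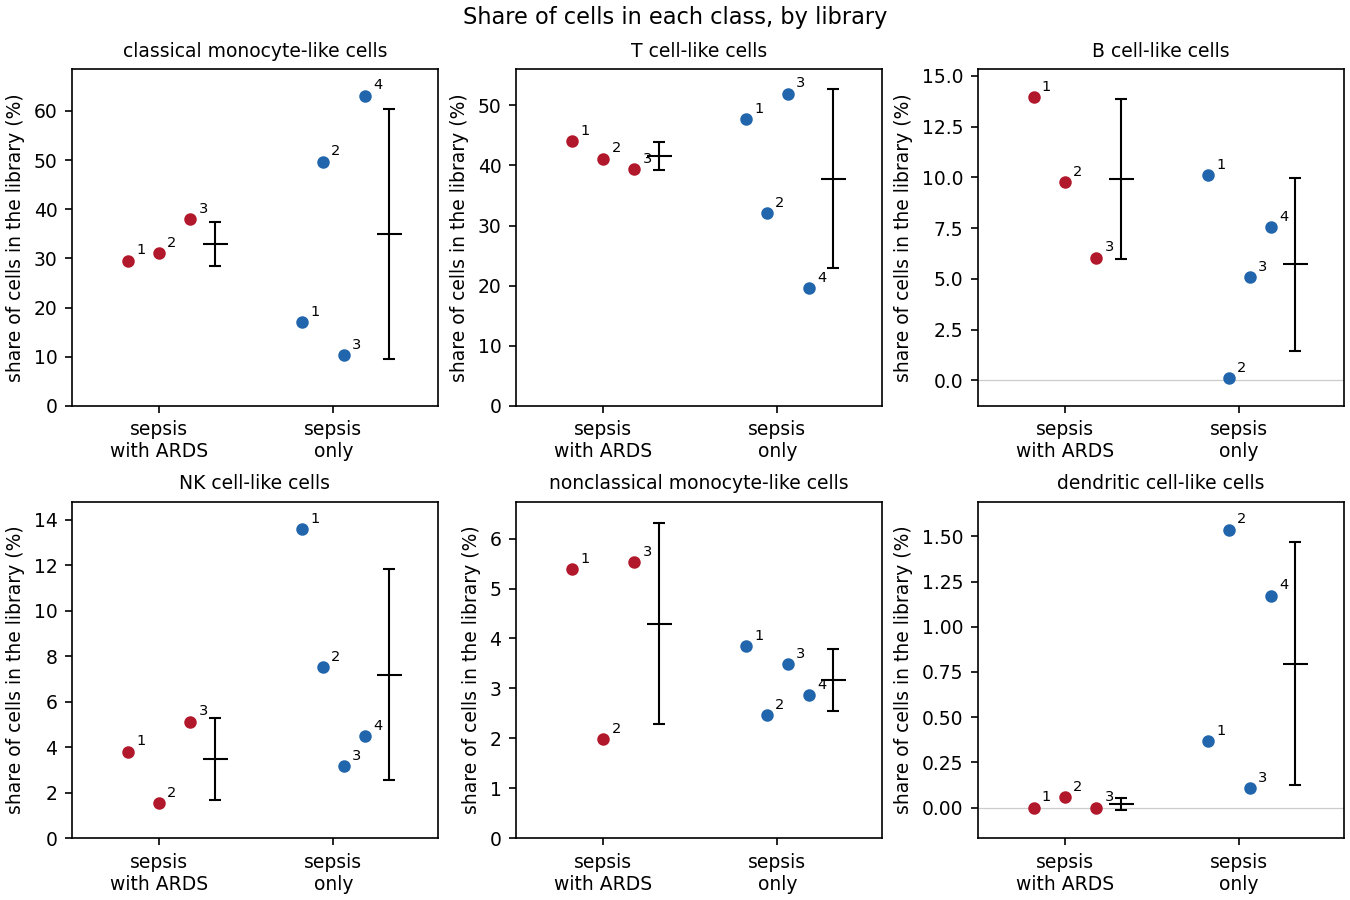
Share of each library's cells in 6 classes, in percent (vertical axis), for sepsis with ARDS (3 libraries) and sepsis only (4 libraries). Each numbered point is 1 library and the bar gives the mean and SD. Classical monocyte-like shares, without the mixed monocyte and platelet clusters, spread from 10.4% to 63.1% in sepsis only. Dendritic cell-like shares stay at or below 0.058% in sepsis with ARDS.

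Before the groups were compared gene by gene, the libraries were set beside each other on log2 CPM of the UMIs summed in each class. CPM is the count scaled to the library's total over the tested genes, adjusted by its TMM factor, except where plain totals are named. In classical monocyte-like, T cell-like, NK cell-like and B cell-like cells, sepsis_ARDS 1 and sepsis_only 3 lay together on 1 side of the largest gap of the first component. That component held 56.6%, 54.9%, 47.7% and 61.5% of the variance. Both libraries lay below or above all other libraries for 40.6% of 8133 genes in monocyte-like cells, 46.1% of 8867 in T cell-like, 40.1% of 3041 in NK cell-like and 50.0% of 3765 in B cell-like cells. The pair was picked on these same genes, so these shares describe it and have no chance level. The list of NF-kB and TNF inflammatory response genes, the transcripts of acute cytokine signalling, averaged 3.18 and 2.97 log2 CPM in T cell-like cells of sepsis_ARDS 1 and sepsis_only 3, and 4.63 to 5.48 in the other 5 libraries. In monocyte-like cells the same list averaged 3.88 and 4.37 against 4.48 to 5.82. The 2 libraries belong to different groups, and the labels record no batch. All CPM values below are means ± SD over the 3 sepsis_ARDS and 4 sepsis_only libraries (3 and 3 in B cell-like cells), and log2 fold changes of genes carry their SE.

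**Figure D2:**
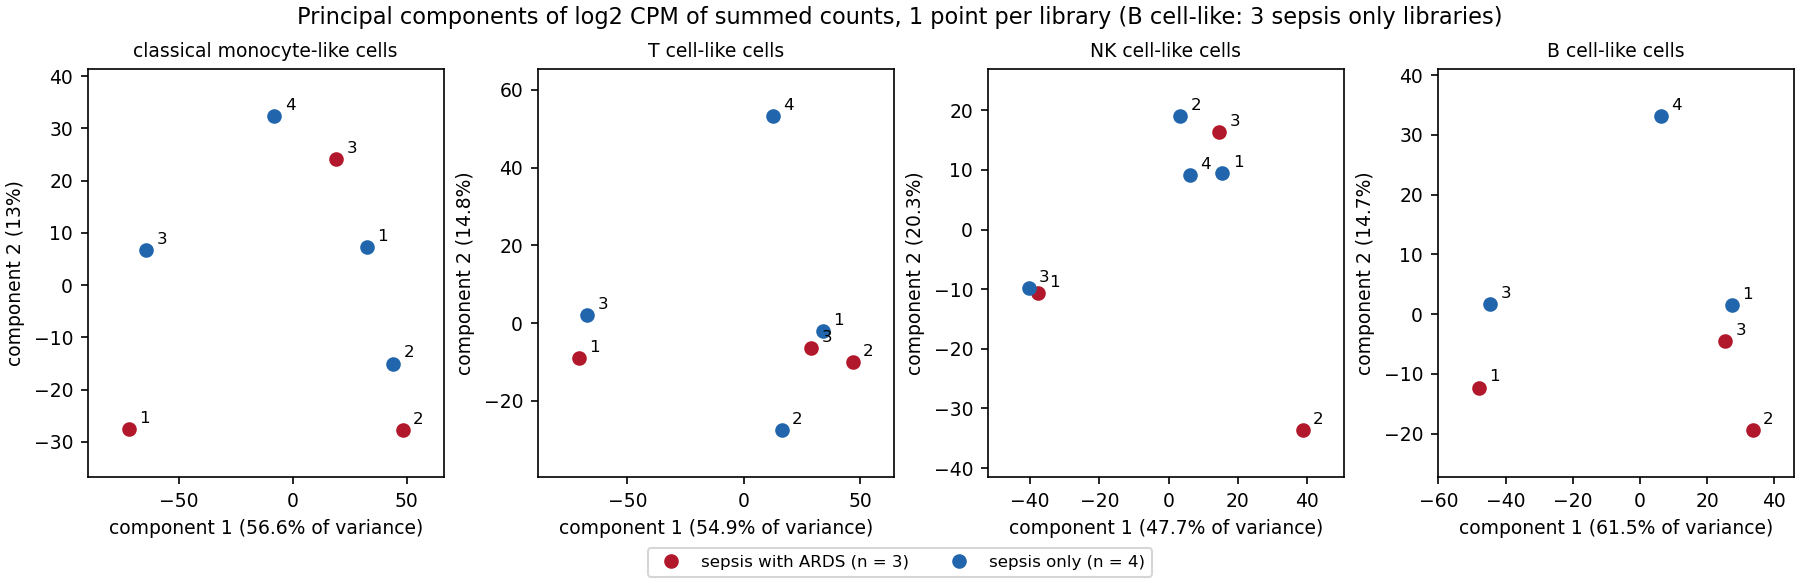
First and second principal components of log2 CPM of summed counts in 4 cell classes, with 1 numbered point per library (axes in component units, with the share of variance). In each class sepsis with ARDS 1 and sepsis only 3 sit together at the low end of the first component, which holds 47.7% to 61.5% of the variance.

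Classical monocyte-like cells are the subject of the series title, which speaks of an early monocyte gene signature in ARDS. Type I interferon-stimulated genes, the antiviral program downstream of interferon receptors, were higher in sepsis_ARDS for 18 of the 18 members tested, with a median log2 fold change of 2.04. ISG15, a ubiquitin-like modifier, averaged 415 ± 644 CPM against 46.6 ± 4.69 CPM (log2 fold change 3.16 ± 1.07, SE). IFI6, an antiviral membrane protein, differed by 2.57 ± 0.95, and OAS2, a sensor of double-stranded RNA, by 3.96 ± 1.59. The list rose by camera (adjusted p = 4.27e-07, and adjusted p = 0.595 with an estimated correlation), and 0 of its members passed adjusted over the list alone or over all genes by edgeR. This rise lay in 1 library. The list averaged 7.82 log2 CPM in sepsis_ARDS 1 and 3.07 to 4.30 in the other 6 libraries. Without sepsis_ARDS 1 the list was lower in sepsis_ARDS (median −0.70, adjusted p = 0.00232 by camera), with ISG15 at −0.12, IFI6 at 0.0095 and OAS2 at −2.38. Without the 2 libraries that stand apart, a check chosen after seeing the data, the median was −0.65 (adjusted p = 0.00378).

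Platelet genes were higher in classical monocyte-like cells of sepsis_ARDS for 11 of 12 members, with a median log2 fold change of 1.33. NRGN, a calmodulin-binding protein abundant in platelets, averaged 231 ± 119 CPM against 95.3 ± 38.2 CPM (1.28 ± 0.47). SDPR, a caveolar protein, differed by 1.63 ± 0.60 (0.90 without sepsis_ARDS 1) and ACRBP by 1.57 ± 0.59 (0.35 without it). The list rose by camera (adjusted p = 8.88e-10, and adjusted p = 0.595 with an estimated correlation). Without sepsis_ARDS 1 its median was 0.52 (adjusted p = 0.029), and without the 2 libraries that stand apart it was 0.43 (adjusted p = 0.0239). With the clusters that hold monocyte and platelet genes together counted as monocytes, a check chosen after seeing the data, the median fell to 0.082 and the call was lost (adjusted p = 0.819 by camera).

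Genes of other blood cells were also higher in the summed counts of monocyte-like cells of sepsis_ARDS. Whether free RNA shared by all cells of a library, or doublets still present, carried these transcripts was not tested. They are not read as expression by monocytes. T and NK lymphocyte genes were higher for 14 of 14 members (median 0.79, adjusted p = 2.37e-04 by camera, and adjusted p = 0.595 with an estimated correlation), among them CD3G, a chain of the T cell receptor complex (3.56 ± 2.04 CPM against 1.55 ± 1.51 CPM, log2 fold change 1.54 ± 0.80). CD2 differed by 1.01 ± 0.64 and TRAC by 1.19 ± 0.86 (0.49 and 0.35 without sepsis_ARDS 1, and TRAC 2.12 without sepsis_only 3). The median was 0.35 without sepsis_ARDS 1 (adjusted p = 0.352), 0.55 without sepsis_only 2 (0.0587) and 0.45 without sepsis_only 4 (0.0937), each ending the call. B and plasma cell genes were higher for 4 of 4 members (median 1.503, adjusted p = 0.00398, and adjusted p = 0.595 with an estimated correlation). CD79A, part of the B cell receptor, averaged 6.74 ± 2.06 CPM against 2.48 ± 1.88 CPM, and IGKC, the kappa light chain, 69.4 ± 108 CPM against 8.30 ± 10.9 CPM. Without sepsis_ARDS 1 the median was −0.40 (adjusted p = 0.618, IGKC −0.10, CD79B −0.70), without sepsis_only 2 it was 1.22 (0.0919), and with the mixed monocyte and platelet clusters 0.17 (0.184).

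Of the lists called lower in classical monocyte-like cells of sepsis_ARDS, MHC class II presentation genes were lower for 9 of 9 members (median −0.47), among them HLA-DPB1 (206 ± 102 CPM against 371 ± 349 CPM, −0.85 ± 0.71), HLA-DQB1 (−1.20 ± 0.96) and HLA-DQA1 (−1.31 ± 0.97). HLA-DQB1 and HLA-DQA1 were −0.23 and −0.16 without sepsis_only 2, and −2.82 each without sepsis_ARDS 2. That list fell by camera (adjusted p = 0.00902, and adjusted p = 0.609 with an estimated correlation). Its median was −0.12 without sepsis_ARDS 3 (adjusted p = 0.833) and 0.064 without sepsis_only 2 (0.692, with HLA-DPB1 at 0.064). It was −1.06 without sepsis_ARDS 2 (4.04e-05) and −0.98 without the 2 libraries that stand apart (4.81e-05), while a term for these 2 libraries gave −0.32 and ended the call (0.0785). Cytosolic ribosomal protein genes were lower for 80 of 89 members (median −0.25, adjusted p = 9.14e-08, and adjusted p = 0.609 with an estimated correlation). Their median was 0.0061 without sepsis_ARDS 1 (adjusted p = 0.917), −0.51 without sepsis_ARDS 2, −0.11 without sepsis_only 2 and −0.078 without the 2 libraries that stand apart (0.172). Nuclear-encoded oxidative phosphorylation genes were lower for 22 of 24 members (median −0.13, adjusted p = 0.00601, and adjusted p = 0.601 with an estimated correlation). UQCRC1, a core subunit of complex III, averaged 95.9 ± 13.1 CPM against 125 ± 13.5 CPM, COX5A differed by −0.43 ± 0.31 and UQCRC2 by −0.51 ± 0.37 (−0.23 and −0.25 without sepsis_ARDS 1). COX5A was −0.71 without sepsis_ARDS 3 and UQCRC2 −0.93 without sepsis_ARDS 2. The median was −0.089 without sepsis_ARDS 1 (adjusted p = 0.427), −0.11 without sepsis_only 4 (0.0948) and −0.10 without the 2 libraries that stand apart (0.172), and −0.23, −0.30 and −0.20 without sepsis_ARDS 2, sepsis_ARDS 3 and sepsis_only 2.

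Apoptosis regulators were higher for 13 of 15 members (median 0.28, adjusted p = 0.0042, and adjusted p = 0.427 with an estimated correlation). PMAIP1 (NOXA), a BH3-only killer protein, averaged 15.5 ± 7.07 CPM against 7.44 ± 2.01 CPM, CASP8, the initiator caspase of death receptors, 38.4 ± 10.3 CPM against 24.4 ± 9.26 CPM, and BBC3 (PUMA) 11.4 ± 2.21 CPM against 7.16 ± 2.86 CPM. The log2 fold changes of PMAIP1 and CASP8 went from 1.05 and 0.65 to 0.64 and 0.40 without sepsis_ARDS 3. Without sepsis_ARDS 3 the median was 0.23 and the call was lost (adjusted p = 0.0885). Over the 25 lists tested in monocytes, fry and camera with an estimated correlation each called 0. In monocyte-like, T cell-like and B cell-like cells 0 members of any list passed adjusted over the list alone, and 0 passed over all genes in any class.

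The other 17 lists did not pass in classical monocyte-like cells. In the JAK-STAT and cytokine feedback list, 8 of 19 members were higher (median −0.31, adjusted p = 0.211), and SOCS3, a feedback inhibitor of cytokine receptors, averaged 117 ± 11.1 CPM against 263 ± 124 CPM (−1.18 ± 0.42). MYC in the same list differed by 1.31 ± 0.67 and JAK2 by 1.91 ± 1.06 (0.25 and −1.29 without sepsis_ARDS 1). In the glycolysis and hypoxia response list 6 of 21 were higher (median −0.16, adjusted p = 0.0548). LDHA, which makes lactate, averaged 290 ± 97.0 CPM against 520 ± 149 CPM and ENO1, an enolase, 308 ± 56.8 CPM against 498 ± 119 CPM. In the cell stress and immediate early list 16 of 21 were higher (median 0.39, adjusted p = 0.163). FOS, an AP-1 subunit, averaged 1341 ± 160 CPM against 768 ± 166 CPM and KLF6 differed by 0.54 ± 0.28 (0.29 without sepsis_ARDS 3), with no overlap between groups for either. HSPA1A, an inducible chaperone, differed by 3.03 ± 1.40, and by −0.89 without sepsis_ARDS 1. In the S100 alarmin and sepsis monocyte list 4 of 14 were higher (median −0.19, adjusted p = 0.615), with VNN2 at 0.93 ± 0.49, RETN (resistin) at −0.71 ± 0.56 and ALOX5AP at −0.69 ± 0.62. VNN2, RETN and ALOX5AP were 0.46, −0.36 and −1.61 without sepsis_ARDS 2, RETN was −1.79 without sepsis_ARDS 3, and ALOX5AP was −0.29 without sepsis_ARDS 1. Medians of the remaining lists were 0.17 for NF-kB and TNF response (13 of 22 higher), 0.24 for MHC class I presentation (8 of 13), −0.25 for glucocorticoid-responsive genes (6 of 15), 0.12 for pattern recognition and inflammasome (16 of 22) and −0.21 for scavenger and phagocytosis receptors (7 of 18). They were −0.38 for neutrophil granule genes (2 of 6), 0.15 for erythroid genes (5 of 5), 0.51 for cytotoxic effector genes (8 of 10), −0.24 for T cell exhaustion and inhibitory receptors (1 of 4), 0.67 for naive and memory T cell genes (5 of 6), 0.23 for cell cycle (4 of 6) and 0.0058 for mitochondrially encoded mRNAs (9 of 13). Coagulation and fibrinolysis genes had a median of 0.017 (5 of 9 higher) while their mean (−0.17) and camera's direction were lower.

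Gene by gene, edgeR called 0 of 8133 genes in classical monocyte-like cells. At an unadjusted p under 0.05 it gave 159 genes (100 higher, 59 lower) where chance gives about 406.7, and DESeq2 gave 0 after adjustment and 194 before it. Among the genes with the smallest p, given as values that did not pass (adjusted p = 1.00 for each), were NRROS, a regulator of reactive oxygen species (22.7 ± 11.6 CPM against 6.74 ± 2.06 CPM, log2 fold change 1.77 ± 0.43), and RHOB, a stress-responsive small GTPase (63.7 ± 61.6 CPM against 13.7 ± 1.75 CPM, 2.22 ± 0.57). RAB11FIP1, a recycling endosome protein, differed by 1.28 ± 0.34 and C16orf54 by 1.13 ± 0.34. MMD differed by 1.598 ± 0.489, GMPR, a GMP reductase, by 1.78 ± 0.56, and CTTN, a cortical actin binding protein, by 2.31 ± 0.74. Without sepsis_ARDS 1, RHOB was 1.03, GMPR 0.78, CTTN 1.39 and MMD 1.03. CTTN was also a leading gene of sub-cluster 28.3, which held platelet and T cell markers. Whether platelet transcripts carried any of these differences was not tested. The non-coding RP11-347P5.1 differed by 1.99 ± 0.48 and RP11-443B7.1 by 1.17 ± 0.36. Lower values were found for PLA2G7, the secreted phospholipase that inactivates platelet-activating factor (3.84 ± 2.25 CPM against 19.58 ± 7.999 CPM, −2.44 ± 0.56), and for IMPDH2, of guanine nucleotide synthesis (12.98 ± 0.977 CPM against 24.1 ± 4.49 CPM, −0.89 ± 0.30). FARSB, a tRNA synthetase subunit, differed by −1.63 ± 0.46, PEBP1, a RAF kinase inhibitor, by −1.04 ± 0.35, and SMARCB1, a chromatin remodeler subunit, by −1.01 ± 0.33. METTL5 differed by −1.27 ± 0.44, CRCP by −1.16 ± 0.37, C20orf196 by −1.15 ± 0.40, AC090498.1 by −1.43 ± 0.47 and KANSL1-AS1 by −2.19 ± 0.58. The groups did not overlap for 277 genes (3.41%), where chance gives 5.71%. Counts below chance here and in the classes below do not show that the groups are alike. The 2 libraries that stand apart belong to different groups, so genes on which both lie outside the rest cannot separate the groups. Without them, a check chosen after seeing the data, 238 of 7912 genes had an unadjusted p under 0.05 by edgeR. In T cell-like, NK cell-like and B cell-like cells the counts were 302 of 8191, 66 of 2433 and 185 of 3506.

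The values of each class rest on different cell clusters in different libraries, so a change within a class was not separated from a difference in its subsets. Cell numbers and percentages of clusters given here are before doublet removal. Most monocyte-like cells of sepsis_ARDS 1 lay in a cluster of their own (1203 of its 1233 cells), whose leading genes included IFI27, IFI6 and ISG15. Those of sepsis_only 4, sepsis_only 2 and sepsis_only 3 lay in clusters that were 97.1%, 97.0% and 98.0% from that library, and those of sepsis_ARDS 2, sepsis_ARDS 3 and sepsis_only 1 shared 1 cluster. T cell-like clusters 13, 9 and 16 were 99.8% from sepsis_ARDS 1, 94.4% from sepsis_only 3 and 86.8% from sepsis_only 2, and cluster 7 held 817 cells of sepsis_ARDS 1, 656 of sepsis_only 3 and 3 of the other libraries. Of NK cell-like clusters, 22 held only sepsis_ARDS 1 and sepsis_only 3 (150 and 113 cells), 23 was 92.4% from sepsis_only 2, and 11 held most NK cell-like cells of sepsis_ARDS 2, sepsis_ARDS 3, sepsis_only 1 and sepsis_only 4. Of B cell-like clusters, 14 was 95.7% from sepsis_ARDS 1 and 10 held 351, 129, 402 and 289 cells of sepsis_ARDS 2, sepsis_ARDS 3, sepsis_only 1 and sepsis_only 4. The 4 B cell-like sub-clusters led by TCL1A were 60.0% to 94.7% from sepsis_only 3. On counts simulated at the fitted spread of these libraries, the same edgeR test recovered 2.99% of 2-fold, 37.3% of 4-fold and 87.9% of 8-fold changes in classical monocyte-like cells.

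**Figure D3:**
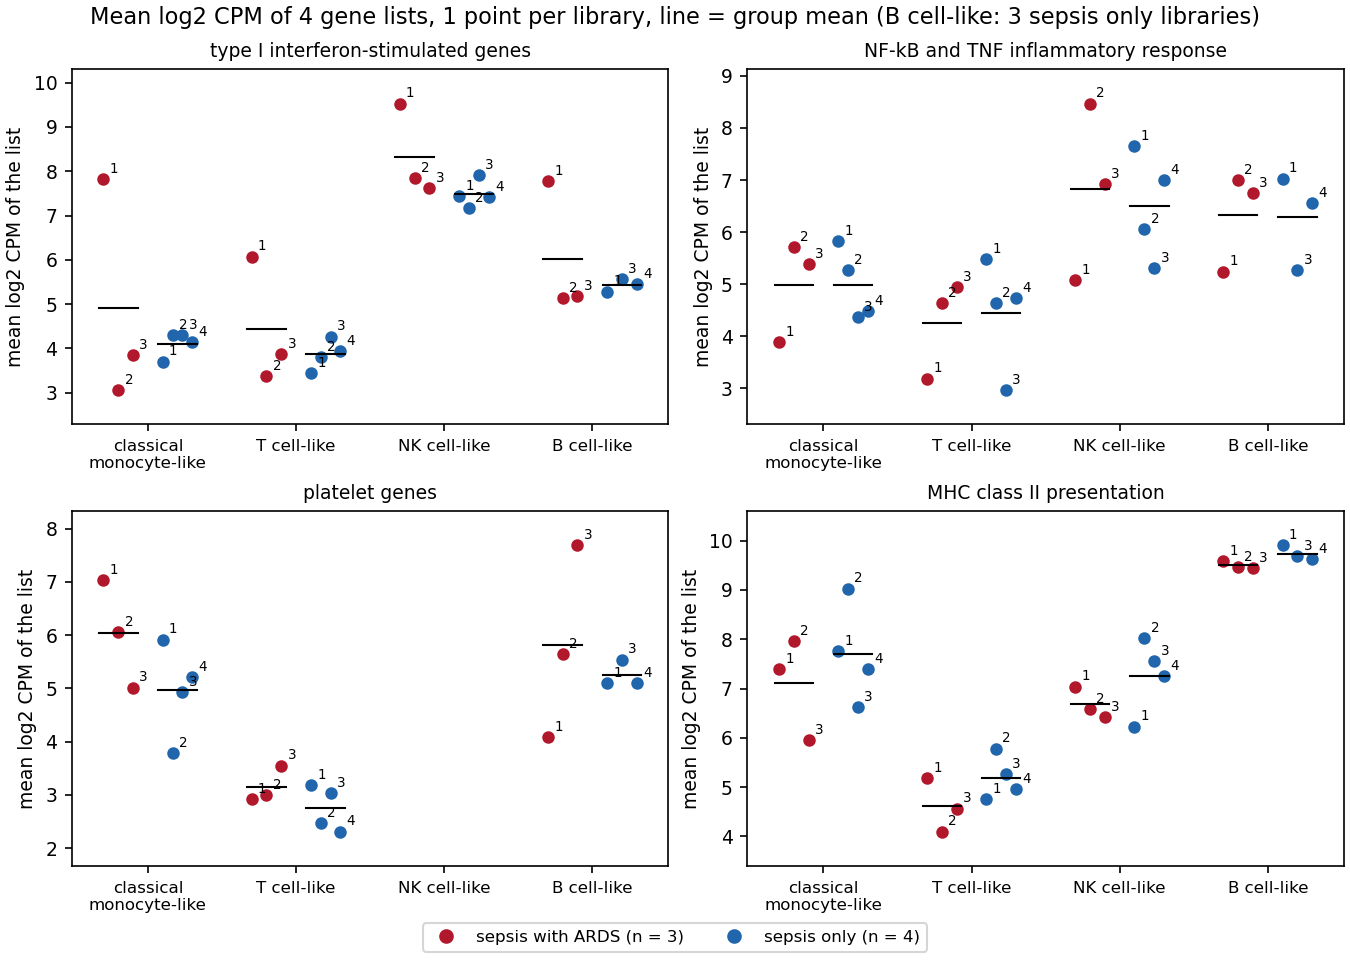
Mean log2 CPM (vertical axis) of 4 gene lists in 4 cell classes, with 1 numbered point per library and a line at the group mean; classes with fewer than 3 measured members are left out. In classical monocyte-like cells the interferon list of sepsis with ARDS 1 is at 7.82 and the other 6 libraries lie between 3.07 and 4.30.

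In T cell-like cells, which lay in clusters of single libraries in part (above), the same contrast asked whether changes reached lymphocytes. Type I interferon-stimulated genes were higher in sepsis_ARDS for 20 of 21 members (median log2 fold change 1.04), among them IFI44L (60.3 ± 99.9 CPM against 3.64 ± 2.69 CPM, 4.12 ± 1.41), IFITM3, which blocks viral entry (1.77 ± 0.64), and EPSTI1 (1.88 ± 0.87). That list rose by camera (adjusted p = 2.32e-07, and adjusted p = 0.718 with an estimated correlation). Without sepsis_ARDS 1 its median was −0.36 (adjusted p = 0.274, IFI44L −0.36, EPSTI1 −0.57, IFITM3 0.37), and without the 2 libraries that stand apart −0.093 (0.763). MHC class II genes were lower for 9 of 9 members (median −0.35, adjusted p = 4.79e-04, and adjusted p = 0.699 with an estimated correlation), with HLA-DQA1 at −1.27 ± 0.79, HLA-DQB1 at −1.02 ± 0.64 and HLA-DRA at −0.77 ± 0.53. HLA-DQA1 was −0.29 without sepsis_only 3, HLA-DRA −0.42 without sepsis_only 2, and HLA-DQB1 −2.43 without sepsis_ARDS 2 and −0.57 without sepsis_ARDS 3. The call was lost without sepsis_only 2 (median −0.22, adjusted p = 0.0871), and the median was −0.96 without sepsis_ARDS 1, −0.18 without sepsis_ARDS 2 and −0.75 without the 2 libraries that stand apart. Platelet genes were higher for 9 of 9 members (median 0.42, adjusted p = 0.00371, and adjusted p = 0.699 with an estimated correlation), with NRGN at 0.80 ± 0.43, TUBB1, the platelet tubulin, at 0.54 ± 0.49 (0.19 without sepsis_ARDS 1) and SPARC at 0.51 ± 0.47 (0.28 without sepsis_ARDS 2). That call was lost without sepsis_ARDS 3 (median 0.085, adjusted p = 0.362), sepsis_only 2 (0.27, 0.0778) or sepsis_only 4 (0.31, 0.0915), and the median was 0.79 without the 2 libraries that stand apart. Whether free platelet RNA, or doublets of T cells and platelets, carried these transcripts in T cell-like cells was not tested. Nor was it tested whether free RNA or doublets carried the MHC class II transcripts there. Ribosomal protein genes were lower for 73 of 91 members (median −0.093, adjusted p = 0.007, and adjusted p = 0.791 with an estimated correlation).

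The ribosomal list in T cell-like cells had a median of 0.23 without sepsis_ARDS 1 and 0.11 without the 2 libraries that stand apart, each called higher by camera (adjusted p = 3.15e-04 and 0.0429), and −0.14 with a term for these 2 libraries (0.0535). It was not called without sepsis_only 1 (0.022, adjusted p = 0.672) or sepsis_only 4 (−0.027, 0.221), and was −0.48, −0.15, −0.15 and −0.21 without sepsis_ARDS 2, sepsis_ARDS 3, sepsis_only 2 and sepsis_only 3. Of 24 lists tested in T cell-like cells the other 20 did not pass, and fry called 0. Cytotoxic effector genes had a median of 0.38 and a mean of 0.19, pattern recognition genes 0.026 and 0.037, both with camera's direction lower. Cell cycle genes had a median of −0.036 and a mean of 0.086. By edgeR 0 of 8867 genes passed in T cell-like cells, with 53 at an unadjusted p under 0.05 (chance about 443.4), and DESeq2 gave 0 (53 unadjusted). The groups did not overlap for 197 genes (2.22%, chance 5.71%).

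In NK cell-like cells, type I interferon-stimulated genes were higher in sepsis_ARDS for 6 of 6 members (median 1.06). IFITM3 averaged 289 ± 257 CPM against 68.1 ± 37.0 CPM (2.16 ± 0.61), ISG15 362 ± 367 CPM against 82.9 ± 67.6 CPM (2.17 ± 0.73) and IFI6 137 ± 110 CPM against 60.3 ± 19.5 CPM (1.26 ± 0.52). The list rose by camera (adjusted p = 2.81e-05, and adjusted p = 0.776 with an estimated correlation), and 2 of its 6 members passed adjusted over the list alone, against 0 over all genes. Without sepsis_ARDS 1 the 3 genes were 1.07, 0.77 and 0.20, the median was 0.54 and the call was lost (adjusted p = 0.327), without sepsis_ARDS 3 it was 2.13, and without the 2 libraries that stand apart 0.51 (adjusted p = 0.0365). GZMK, a granzyme of the less differentiated cytotoxic cells, averaged 111 ± 42.2 CPM against 25.5 ± 14.2 CPM (2.17 ± 0.53). Every sepsis_ARDS library lay above every sepsis_only library, and it was the 1 cytotoxic effector gene of 14 that passed adjusted over the list alone (adjusted p = 0.0263 by edgeR). With each cell named by its own markers the difference was 0.29 (unadjusted p = 0.628). GZMK is also expressed by T cells, and in these NK cell-like cells 3 of 4 naive and memory T cell genes were higher (median 0.74, adjusted p = 0.0682 by camera, and adjusted p = 0.776 with an estimated correlation), which did not pass. The libraries' NK cell-like cells lay in different clusters. FGFBP2, a marker of mature NK cells, differed by −0.83 ± 0.47 and GZMB by 0.68 ± 0.47 (−1.44 and −0.031 without sepsis_ARDS 1). The cytotoxic list as a whole did not pass (10 of 14 higher, median 0.16, adjusted p = 0.135 by camera).

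MHC class II genes were lower in NK cell-like cells of sepsis_ARDS for 5 of 6 members (median −0.44, adjusted p = 0.0321, and adjusted p = 0.776 with an estimated correlation), with HLA-DQB1 at −2.84 ± 0.96, HLA-DRA at −0.92 ± 0.66 (−0.51 without sepsis_only 2) and HLA-DRB1 at −0.54 ± 0.64 (0.021 without sepsis_only 3). The median was 0.030 without sepsis_only 2 (adjusted p = 0.964), and the call was also lost without sepsis_ARDS 1 (−0.81, 0.0505), sepsis_ARDS 3 (−0.35, 0.608), sepsis_only 3 (−0.21, 0.487), the 2 libraries that stand apart (−0.52, 0.162) or the low count filter (−0.57, 0.192). It was −0.29 without sepsis_ARDS 2 and −0.77 without sepsis_only 1. Whether free RNA, or doublets still present, carried the MHC class II transcripts in NK cell-like cells was not tested. Mitochondrially encoded mRNAs were lower for 11 of 12 members (median −0.37, adjusted p = 0.0137, and adjusted p = 0.776 with an estimated correlation). That call was lost without sepsis_ARDS 1 (−0.22, adjusted p = 0.554), sepsis_only 4 (−0.16, 0.159) or the 2 libraries that stand apart (−0.41, 0.0847), and the median was −0.67 without sepsis_ARDS 3 and −0.56 without sepsis_only 3. Ribosomal protein genes were lower for 72 of 84 members (median −0.15, adjusted p = 0.00522, and adjusted p = 0.789 with an estimated correlation). Their median was 0.083 without sepsis_ARDS 1 (adjusted p = 0.136), −0.088 without sepsis_only 2 (0.096), −0.061 without sepsis_only 4 (0.128) and −0.028 without the 2 libraries that stand apart (0.99). It was −0.32, −0.39 and −0.27 without sepsis_ARDS 2, sepsis_ARDS 3 and sepsis_only 3.

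The other 14 of the 18 lists tested in NK cell-like cells did not pass, and fry called 0. S100 alarmin genes had a median of −0.26 with camera's direction higher, oxidative phosphorylation genes a median of 0.014 with camera's direction lower, and stress and immediate early genes a median of 0.18 and a mean of −0.021. By edgeR 0 of 3041 genes passed in NK cell-like cells, with 32 at an unadjusted p under 0.05 (chance about 152), and DESeq2 gave 0 (26 unadjusted). The groups did not overlap for 79 genes (2.60%, chance 5.71%). The summed NK cell-like counts ranged from 73133 to 921834 UMIs per library, and the test recovered 83.3% of simulated 8-fold and 4.48% of 2-fold changes.

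In B cell-like cells sepsis_only 2 had 4 cells and was left out, so 3 libraries stood against 3, with most cells of sepsis_ARDS 1 and of sepsis_only 3 in clusters apart from those of the other libraries. Interferon-stimulated genes were higher in sepsis_ARDS for 7 of 7 members (median 1.48, adjusted p = 0.0335 by camera, and adjusted p = 0.926 with an estimated correlation), with ISG15 at 2.28 ± 1.12, EIF2AK2, the RNA-activated kinase PKR, at 38.6 ± 40.6 CPM against 14.7 ± 5.50 CPM and IRF7 at 1.48 ± 0.82. Without sepsis_ARDS 1 the median was −0.13 (adjusted p = 0.559, IRF7 −0.23, ISG15 0.0053, EIF2AK2 0.042), without sepsis_only 1 it was 1.27 (0.0663), and without the 2 libraries that stand apart 0.074 (0.906). MHC class I presentation genes were higher for 11 of 13 members (median 0.50, adjusted p = 0.0296, and adjusted p = 0.926 with an estimated correlation). NLRC5, their transactivator, averaged 23.5 ± 4.80 CPM against 9.85 ± 3.02 CPM with no overlap between groups. TAP1, the peptide transporter, differed by 1.29 ± 0.85 (−0.40 without sepsis_ARDS 1) and PSMB9, an immunoproteasome subunit, by 1.39 ± 0.93 (−0.35 without it). That list's median was −0.099 without sepsis_ARDS 1 (adjusted p = 0.839), 0.42 without sepsis_only 1 (0.198), 0.27 without sepsis_only 4, 0.29 without the 2 libraries that stand apart (0.825) and 0.47 without the low count filter (0.0593).

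Glucocorticoid-responsive genes were lower in B cell-like cells for 7 of 8 members (median −0.84, adjusted p = 0.0237, and adjusted p = 0.926 with an estimated correlation), with the transcription factor ZBTB16 at −1.76 ± 0.85, TXNIP at −0.89 ± 0.57 and KLF9 at −1.18 ± 0.77. ZBTB16 and KLF9 were −1.12 and −0.65 without sepsis_ARDS 1, ZBTB16 and TXNIP −3.57 and −1.796 without sepsis_ARDS 2, and TXNIP −0.52 without sepsis_ARDS 3. That call was lost without sepsis_ARDS 1 (−0.65, adjusted p = 0.559), sepsis_only 1 (−0.89, 0.124) or sepsis_only 4 (−0.34, 0.666), and the median was −1.30 without sepsis_ARDS 2. Apoptosis regulators were higher for 10 of 10 members (median 0.30, adjusted p = 0.0346, and adjusted p = 0.926 with an estimated correlation). BAK1, a pore-forming effector, averaged 18.1 ± 3.62 CPM against 8.15 ± 2.19 CPM with no overlap, CFLAR, an inhibitor of caspase 8, differed by 1.07 ± 0.52 and CASP8 by 0.50 ± 0.45 (0.056 without sepsis_ARDS 3). The apoptosis call was lost without sepsis_ARDS 1 (0.47, adjusted p = 0.165), sepsis_ARDS 2 (0.24, 0.121), sepsis_ARDS 3 (0.084, 0.166), sepsis_only 1 (0.34, 0.198), sepsis_only 3 (0.23, 0.159), the 2 libraries that stand apart (0.50, 0.144) or the low count filter (0.17, 0.0593), and stood without sepsis_only 4 (0.49, 0.00377). Ribosomal protein genes were lower for 72 of 85 members (median −0.12, adjusted p = 0.0237, and adjusted p = 0.967 with an estimated correlation). Their median was 0.080 without sepsis_ARDS 1 (adjusted p = 0.505), −0.042 without sepsis_only 1 (0.796), −0.093 without sepsis_only 4 (0.424), −0.054 without the 2 libraries that stand apart (0.848) and −0.16 without the low count filter (0.0668). It was −0.34, −0.24 and −0.26 without sepsis_ARDS 2, sepsis_ARDS 3 and sepsis_only 3.

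B and plasma cell genes did not pass as a list in B cell-like cells (9 of 14 higher, median 0.16, adjusted p = 0.936). IGHA1, the constant region of class-switched IgA, averaged 278 ± 173 CPM against 99.9 ± 38.9 CPM (1.47 ± 0.59, and 0.90 without sepsis_ARDS 2). VPREB3 averaged 43.0 ± 20.8 CPM against 127 ± 93.3 CPM (−1.53 ± 0.67, and −0.81 without sepsis_only 3), and TCL1A, a gene of naive B cells, 29.9 ± 24.6 CPM against 229 ± 351 CPM (−2.85 ± 1.29, and 0.26 without sepsis_only 3). The other lists of the 19 tested did not pass, and fry called 0. JAK-STAT genes (median 0.0029, mean −0.053), glycolysis genes (0.017, −0.065) and stress genes (0.066, −0.12) had a median and a mean of opposite sign. By edgeR 0 of 3765 genes passed in B cell-like cells, with 64 at an unadjusted p under 0.05 (chance about 188.2), and DESeq2 gave 0 (66 unadjusted). The groups did not overlap for 248 genes (6.59%, chance 10%).

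The last comparisons asked whether the difference between groups was itself different in monocytes and T cells, and what all cells summed show without any naming. The log2 fold changes of classical monocyte-like and T cell-like cells correlated across 7091 genes with r = 0.377, where genes are not independent replicates. By limma 0 genes differed in their change between the 2 classes, with 117 at an unadjusted p under 0.05 (chance about 354.6). With all PBMC summed, edgeR called 0 of 11844 genes, with 116 at an unadjusted p under 0.05 (73 higher, 43 lower, chance about 592.2), and DESeq2 called 0 (146 unadjusted). The groups did not overlap for 282 genes (2.38%, chance 5.71%).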

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

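The tests of lower NF-kB and of lower stress and immediate early transcription in 2 libraries and the setting with mixed monocyte and platelet clusters were chosen only after the result was seen. Among 150 groups of 4 libraries, 6 values lay farther from the rest than a limit that chance passes in about 1 group of 20 (7.5 expected), by Dixon's ratio of the gap to the whole range. All 6 were single sepsis_only libraries, since the 3 libraries of sepsis_ARDS are too few for this check. In NK cell-like cells the glycolysis and hypoxia list averaged 7.25 log2 CPM in sepsis_only 4 against 7.42 to 7.43 in the others (ratio 0.937). The oxidative phosphorylation list averaged 8.38 in sepsis_only 3 against 7.88 to 7.91 (0.932), and IFI6 was 6.58 against 5.78 to 5.88 log2 CPM in the same library (0.875). In classical monocyte-like cells the glycolysis list averaged 6.64 in sepsis_only 3 against 7.22 to 7.28 (0.914), and CTTN was 0.94 log2 CPM in sepsis_only 2 against 2.77 to 2.90 (0.934). SPARC in T cell-like cells was 1.12 log2 CPM in sepsis_only 4 against 2.22 to 2.45 (0.8291).

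The first pattern is that sepsis_ARDS 1 and sepsis_only 3, of different groups, stand apart together in every class tested. Sequencing depth is argued against, since after thinning to equal cells and 1000 UMIs per cell the pair stayed alone beyond the largest gap in 4 of 4 classes. The deposited cells of the pair held a median of 935 and 1057 genes, against 611 to 912 in the other libraries. What set this difference was not tested. Ribosomal protein and mitochondrial genes taking the counts are argued against too, with the pair still alone in 4 of 4 classes without these genes. Lower NF-kB transcription in the 2 libraries may be part of it: both lay below every other library on the NF-kB list in 4 of 4 classes. In NK cell-like cells it averaged 5.07 and 5.30 log2 CPM against 6.06 to 8.47, and in B cell-like cells 5.24 and 5.27 against 6.55 to 7.03. The gap was narrowest in monocyte-like cells (values above). The pair was picked on these same values, and both libraries lay below all others for 1679 of 8133 genes in monocyte-like cells. The NF-kB list therefore describes the pattern and is no separate test of a cause. On the cell stress and immediate early list both libraries lay below every other library in 3 of 4 classes. In monocyte-like cells sepsis_ARDS 1 was at 5.49 log2 CPM, above the 5.29 of sepsis_only 4, and its FOS (1521 CPM) and KLF6 (191.7 CPM) were above those of every sepsis_only library, so a part of that program in the pattern stays open. Whether handling of the samples or the state of the patients set these levels stays open, since the labels give no batch; the pair spans both groups.

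The second pattern is the higher type I interferon list in sepsis_ARDS. Free RNA shared by all cells of a library is argued against as the source of the list's level in classical monocyte-like cells only. In the library with the highest values the CPM of 16 list genes was 2.62 times higher there than in T cell-like cells by the median. These CPM carry a TMM factor of 1.31 in monocyte-like and 1.62 in T cell-like cells of that library, which raises the ratio. Free RNA alone would therefore give a ratio somewhat above 1, and the ratio on plain totals was not computed. For T cell-like, NK cell-like and B cell-like cells this ratio cannot decide, since list transcripts carried into them as free RNA could leave the same ratio. That 1 library carries the list is borne out in classical monocyte-like cells: without it the median log2 fold change was −0.703. Chance could not be excluded for the list's mean log2 fold change of 2.18 in these cells, since 24 of 35 splits of the libraries gave one at least as large in size (highest other 2.70). In T cell-like and B cell-like cells the median was also below 0 without that library (−0.36 and −0.13). In NK cell-like cells it was 0.54 without it (adjusted p = 0.327 by camera) and 0.51 without the 2 libraries that stand apart (0.0365), so for that class the question stays open. The design's own explanation, ARDS, stays untested.

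The third pattern is the higher platelet list in classical monocyte-like cells of sepsis_ARDS. Free platelet RNA shared by all cells is argued against by the excess of PPBP and PF4, given as CPM of the plain totals. It was 679 CPM in monocyte-like and 21.2 CPM in T cell-like cells, a ratio of 0.0312. Platelets attached to some monocytes, or doublets of both, could account for part of it and cannot be told apart from a change within monocytes. Without monocytes that held 2 or more UMIs of PPBP and PF4, the median log2 fold change of the other 10 platelet genes went from 1.42 to 0.998, a ratio of 0.704, between the limits set for either reading. The mixed monocyte and platelet clusters were left out of the class and held 2, 398 and 26 cells of sepsis_ARDS 1, 2 and 3. They held 125, 158, 292 and 15 cells of sepsis_only 1, 2, 3 and 4. The main monocyte cluster of sepsis_ARDS 1 scored 4.97 on the monocyte and 2.56 on the platelet list and kept its name. With the mixed clusters counted in, the median of the whole list was 0.082 and the call was lost. The rise therefore depends on which cells count as monocytes.

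Other splits of the libraries tested the counts themselves. The real split gave 0 genes by edgeR in monocyte-like cells and all 35 of 35 splits gave as many or more (highest other 1040). In T cell-like, NK cell-like and all PBMC summed the count of splits was also 35 of 35 (highest other 960, 140 and 794), and for the difference between monocytes and T cells 35 of 35 (highest other 71). A count of 0 cannot exclude chance. At an unadjusted p under 0.05 edgeR gave 159, 53, 32 and 116 genes in those 4 fits and limma 117 for the difference, with 0 by DESeq2 after adjustment in the 4 fits. In the edgeR fits the highest counts came from a split that puts sepsis_ARDS 1 and sepsis_only 3 together in the smaller group. This restates that the pair stands apart, since it was picked on these same genes. For called lists chance could not be excluded in monocyte-like (8 lists, 25 of 35 splits, highest other 14), T cell-like (4 lists, 33 of 35, highest other 14) or NK cell-like cells (4 lists, 24 of 35, highest other 9). In B cell-like cells the 10 splits are too few for a share under 0.05: 10 gave at least the 0 genes (highest other 229, 64 genes unadjusted, 0 by DESeq2) and 4 gave at least the 5 lists (highest other 10).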

How the results depend on the processing

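The settings for the 2 libraries that stand apart (sepsis_ARDS 1 and sepsis_only 3) and with mixed monocyte and platelet clusters were chosen only after the result was seen; the others were planned. Of the alternative values for named genes, 1505 kept direction and side of the threshold, 20 reversed and 1 newly passed (TCL1A in B cell-like cells with no low count filter). No named gene passed in the main fits, so keeping the side of the threshold says little. IFI6 in monocyte-like cells, 2.57 in the main fit and 0.0095 without sepsis_ARDS 1, counts as kept. For called lists, whose direction here is camera's, 185 values held, 99 kept direction but no longer passed and 13 reversed. The count of genes by edgeR stayed at 0 in monocyte-like, T cell-like and all PBMC summed under every setting run, DESeq2 included, as did that of the difference between monocytes and T cells. In NK cell-like and B cell-like cells it was 11 and 15 without the low count filter and 0 under every other setting run. The cause was not tested for any of these moves. The smallest sums were those of NK cell-like cells, from 73133 UMIs per library. B cell-like cells could not be run without sepsis_only 2, which is not in that comparison.

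Lists called: an estimated correlation gave 0 and fry 0 in each of the 4 classes. With no low count filter there were 8 in T cell-like and 3 in B cell-like cells, and without the 2 libraries 8 in T cell-like and 2 in B cell-like cells. Leaving out 1 library at a time gave 2 (without sepsis_only 4) to 10 (without sepsis_ARDS 2 or sepsis_only 3) in T cell-like, 2 (without sepsis_only 2) to 7 (without sepsis_only 4) in NK cell-like and 0 (without sepsis_only 1) to 6 (without sepsis_ARDS 3 or sepsis_only 3) in B cell-like cells. In monocyte-like cells it gave 6 to 12.

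Without the 2 libraries that stand apart, log2 fold changes reversed for ISG15 (−0.062), IFI6 (−0.19) and JAK2 (−0.76) in monocyte-like cells and for IFI44L (−0.44) and EPSTI1 (−0.41) in T cell-like cells. The interferon list reversed in monocyte-like (−0.65), T cell-like (−0.093) and, by camera's direction, B cell-like cells (0.074), and the ribosomal list in T cell-like cells (0.11). With a term for the 2 libraries in place of leaving them out, the calls of the MHC class II list in monocyte-like cells (−0.32, adjusted p = 0.0785) and of the ribosomal list in T cell-like cells (−0.14, 0.0535) were lost and all other called lists stayed called, the interferon list among them (0.63, 0.60, 0.89 and 0.79 in monocyte-like, T cell-like, NK cell-like and B cell-like cells).

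With 1 library left out at a time, the values that reversed are given as lowest to highest. In monocyte-like cells they were −0.12 to 3.64 for ISG15, −2.38 to 4.48 for OAS2, −1.29 to 2.50 for JAK2, −0.89 to 4.45 for HSPA1A, −0.10 to 4.72 for IGKC and −0.70 to 1.90 for CD79B, each lowest without sepsis_ARDS 1. HLA-DPB1 was −1.25 to 0.064 (highest without sepsis_only 2). The interferon list was −0.70 to 2.70 and the ribosomal list −0.51 to 0.0061, both reversed without sepsis_ARDS 1. In T cell-like cells IFI44L was −0.36 to 4.70, EPSTI1 −0.57 to 2.36, the interferon list −0.36 to 1.53 and the ribosomal list −0.48 to 0.23, all reversed without sepsis_ARDS 1. In NK cell-like cells GZMB was −0.031 to 0.98 and the ribosomal list −0.39 to 0.083 (reversed without sepsis_ARDS 1), the MHC class II list −0.81 to 0.030 (reversed without sepsis_only 2) and HLA-DRB1 −0.90 to 0.021 (reversed without sepsis_only 3). In B cell-like cells IRF7 was −0.23 to 1.80, TAP1 −0.40 to 1.79, PSMB9 −0.35 to 2.26, the interferon list −0.13 to 1.95, the MHC class I list −0.099 to 0.74 and the ribosomal list −0.34 to 0.080, all reversed without sepsis_ARDS 1. TCL1A was −3.92 to 0.26 (reversed without sepsis_only 3).

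Shares, in points of percent, sepsis_ARDS minus sepsis_only: leaving out 1 library gave −10.4 (without sepsis_only 3) to 7.22 (without sepsis_only 4) for classical monocyte-like cells, −2.37 (without sepsis_only 4) to 8.42 (without sepsis_only 3) for T cell-like cells and −4.73 (without sepsis_only 4) to 2.19 (without sepsis_only 3) for the nonclassical share of monocytes. The B cell-like share differed by 4.19 points and by 2.18 without sepsis_ARDS 1, the NK cell-like share by −3.70 and by −1.56 without sepsis_only 1, the nonclassical share of all cells by 1.13, by 0.52 without sepsis_ARDS 3 and by 2.30 without sepsis_ARDS 2, and the plasmacytoid share by 0.137, by 0.070 without sepsis_ARDS 1 and by 0.233 without sepsis_ARDS 2. On a log odds scale the classical share differed by 0.087 and the nonclassical share of monocytes by 0.040, both reversed. In points of percent again, the nonclassical share of monocytes also reversed without the 2 libraries that stand apart (0.159). No share passed under any of these settings.

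With the replicate number as a block, the classical share differed by 7.22 points and the T cell-like share by −2.37, both reversed; this block holds sepsis_only 4 out, having no partner. The numbers name different patients, so they are no pairing: deviations of same-numbered libraries correlated across genes at −0.733 to 0.536. With the block 0 genes passed in any comparison, and 7, 3, 6 and 6 lists passed in monocyte-like, T cell-like, NK cell-like and B cell-like cells. In B cell-like cells sepsis_only 2 was left out, so sepsis_ARDS 2 had no partner either. The blocked contrast there rests on the libraries numbered 1 and 3 only. The lists whose call was lost with the block were oxidative phosphorylation in monocyte-like cells (−0.14, adjusted p = 0.0932), platelet (0.26, 0.0676) and ribosomal genes (−0.12, 0.138) in T cell-like cells, and mitochondrially encoded (−0.18, 0.445) and ribosomal genes (−0.15, 0.0829) in NK cell-like cells.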

Other observations

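The test of a shift from naive to memory B cells was written before its values were seen, but the idea came from IGHA1, VPREB3 and TCL1A in the same libraries. Over 7 naive and 7 memory genes not looked at before, the memory minus naive mean was 0.53, −1.41 and −0.55 log2 units in B cell-like cells of sepsis_ARDS 1, 2 and 3 and −2.23, −1.17 and −1.69 in those of sepsis_only 1, 3 and 4. The difference between group means was 1.22, and the groups overlapped. The highest value was that of sepsis_ARDS 1, which stands apart, and without it the difference is smaller. A shift from naive to memory B cells may therefore be present, and 3 libraries against 3 leave it open.

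HBB, the beta chain of hemoglobin, was chosen after its values were seen and is given as CPM of the plain totals, before doublet removal. It lay at 926 to 1189 CPM in all 4 classes of sepsis_ARDS 1 and at 794 to 1172 CPM in those of sepsis_only 2, and at 6.70 to 69.2 CPM in every class of the other 5 libraries. Cell stress and immediate early genes averaged 4.63 and 4.83 log2 CPM in T cell-like cells of sepsis_ARDS 1 and sepsis_only 3 and 5.96 to 6.55 in the other libraries. In B cell-like cells they averaged 5.42 and 5.56 against 7.09 to 7.33, and in NK cell-like cells 6.88 and 6.33 against 7.48 to 8.85. In monocyte-like cells they averaged 5.49 and 5.13 against 5.29 to 6.18, with HSPA1A at 306.1 and 40.5 CPM against 3.01 to 9.13 CPM. Monocyte and platelet mixed clusters held 4.31 ± 6.31% of the cells in sepsis_ARDS and 4.09 ± 3.10% in sepsis_only (exact permutation p = 0.943), and platelet-like cells 2.05 ± 0.51% and 2.41 ± 2.46% (exact permutation p = 0.943).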
